A study of Mus musculus with 23 samples.

How the data were processed

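The series held 23 arrays of total RNA from sorted mouse CD4+ T cells, in 4 groups by CD25 and CD49f. The deposited table held log2 expression values of 45101 probe sets per array. Per the submitters' processing notes, the authors made these with RMA, whose version is not given in the sources used here. No further scaling was applied before the comparisons. The labels give biological replicate numbers and say that all mice were female. The number of arrays per group limits the precision.

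Probe sets were paired with genes through the array annotation: 34958 named a single gene, 932 named several and 9211 named none. Of the 34958, 34754 matched by Entrez identifier to the table of mouse RefSeq genes (assembly GRCm38.p6) and 204 did not. For a gene with several probe sets, of which there were 9012, the probe set with the highest mean over the 23 arrays was used, which left 18194 genes. Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes), with the 4 groups in a single fit, and p-values were adjusted by the Benjamini-Hochberg method. The comparisons were CD49f within CD25+ and within CD25- cells, CD25 within CD49f+ and within CD49f- cells, and their interaction. A gene was called at an adjusted p under 0.05. Gene lists were tested with camera at its preset correlation of 0.01, adjusted over the 31 lists of a comparison, and again with a correlation estimated per list. Camera p-values below are those of the preset correlation unless stated otherwise. With the estimated correlation those of the most strongly called lists were far larger. The fry test was run as well. Its p-value tests whether the genes of a list move on balance one way, its mixed p-value whether they change in either direction, and neither compares a list with other genes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

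The comparisons, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule named Il2ra, Itga6 and Foxp3 in every comparison, the 8 largest increases and 8 largest decreases among called genes of each pairwise comparison (passing over clone and model numbers), up to 4 called members per list with the smallest p (or 2 uncalled, as values only), the 8 smallest p-values of the interaction, and Xist with Y-linked genes as a check of the labelled sex. The lists were Treg identity, Treg suppressive effectors, naive and lymphoid-homing, effector and memory, integrin genes, laminin genes and other laminin receptors, chemokine receptors, Th1, Th2, Th17, Tfh, TCR-induced early genes, IL-2 and STAT5 targets, cell cycle, interferon response, glycolysis, cholesterol biosynthesis, TNF receptor superfamily, markers of B cells, plasma cells, myeloid and dendritic cells, neutrophils, NK cells, CD8 T cells, gamma delta and NKT cells, platelets and megakaryocytes, erythroid cells, stromal and endothelial cells and thymocytes, heat shock and dissociation stress, and ribosomal proteins. Of 636 list members, 568 were measured and 68 were not. Lists share genes, so the 568 measured members were 495 different genes, and shifts of lists that share genes are not independent. Fos, Jun and Egr1 are on both the TCR-induced early and the heat shock and dissociation stress lists.

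The fit was tested on simulated data of 18194 genes with known log2 changes. Noise was drawn independently for each gene and array, with the gene's fitted spread, and only a small part of the genes was changed. Correlation between genes and arrays that stand apart were not simulated, so the rates below do not cover these. For CD25+CD49f+ against CD25+CD49f-, 53.7% of genes changed by 0.5, 97% by 1 and 98.5% by 2 were called, with 9 false calls. For CD25-CD49f+ against CD25-CD49f-, 68.7% of genes changed by 0.5, 98.5% by 1 and 100% by 2 were called, with 8 false calls. For CD25+CD49f+ against CD25-CD49f+, 65.7% of genes changed by 0.5, 97% by 1 and 100% by 2 were called, with 10 false calls. For CD25+CD49f- against CD25-CD49f-, 64.2% of genes changed by 0.5, 97% by 1 and 100% by 2 were called, with 9 false calls. For the interaction, 28.4% of genes changed by 0.5, 86.6% by 1 and 95.5% by 2 were called, with 7 false calls.

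The alternatives were leaving out each array, a replicate block (fixed or random), array weights, a robust trended eBayes, quantile, median and cyclic loess scaling, other ways of joining the probe sets of a gene, every probe set, the brighter genes only, the compared groups alone, stricter thresholds, camera with an estimated correlation and fry. Added after the data were seen were fits without the 4 arrays that stood apart, with Y-linked transcripts as a covariate, within arrays with or without them, and with the Actb 3' to 5' difference as a covariate. An array counted as Y-linked or Xist positive above log2 levels of 6 and 8. Random splits of the arrays, 100 per comparison with the real one, were fitted in the same way.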

Results

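Gene expression was measured on oligonucleotide arrays in mouse CD4+ T cells sorted by the surface proteins CD25, the alpha chain of the interleukin-2 receptor, and CD49f, the integrin alpha 6 chain. The 23 arrays covered 4 gates, with 7 arrays of CD25-CD49f- cells, 7 of CD25-CD49f+ cells, 5 of CD25+CD49f- cells and 4 of CD25+CD49f+ cells. The number of arrays limits the precision, and the median standard error of a log2 difference was 0.124 within CD25+ cells and 0.099 within CD25- cells. All differences below are log2 values with their standard errors, calls are limma adjusted p under 0.05 over 18194 genes, and the p-values measure the spread between these samples. No 2 arrays held the same values, and the highest correlation between 2 arrays of a group was 0.996.

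The transcripts of the sort markers and of Foxp3, the transcription factor of regulatory T cells (Treg cells), were compared first. Il2ra, which codes CD25, had a mean log2 expression of 5.42 ± 0.20 (SD, n = 7) in CD25-CD49f- cells, 6.84 ± 0.24 (SD, n = 7) in CD25-CD49f+ cells, 9.69 ± 0.16 (SD, n = 5) in CD25+CD49f- cells and 9.60 ± 0.18 (SD, n = 4) in CD25+CD49f+ cells. Foxp3 averaged 4.74 ± 0.32, 8.25 ± 0.22, 9.79 ± 0.08 and 9.85 ± 0.20 (SD) in the same order. Itga6, which codes CD49f, averaged 9.79 ± 0.16, 9.36 ± 0.08, 9.64 ± 0.23 and 9.81 ± 0.03 (SD). The Itga6 transcript was lower in CD25-CD49f+ than in CD25-CD49f- cells (-0.44 ± 0.08, adjusted p = 3.21e-04) and was not called between CD25+CD49f+ and CD25+CD49f- cells (0.16 ± 0.10, adjusted p = 0.88). A further Itga6 probe set gave -0.42 ± 0.23 (adjusted p = 0.308 over all probe sets) in CD25- cells and 0.40 ± 0.28 (adjusted p = 1) in CD25+ cells.

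**Figure D1:**
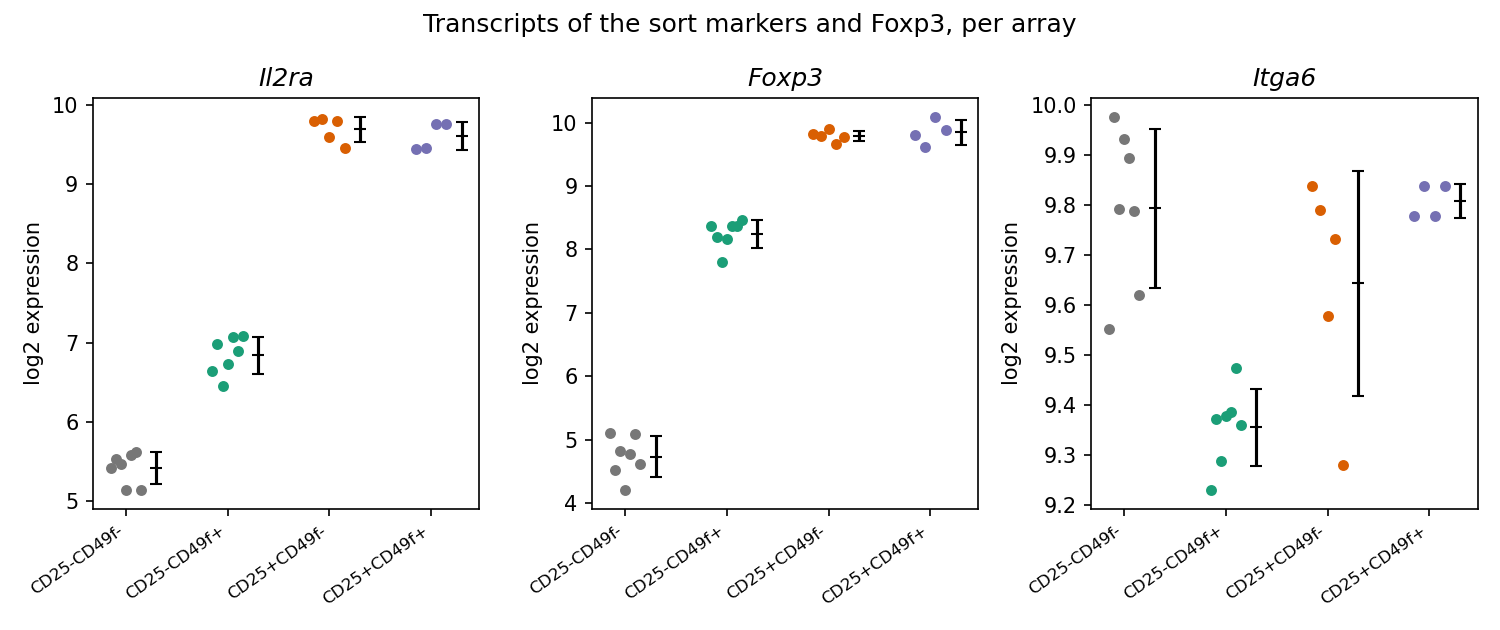
Log2 expression of Il2ra, Foxp3 and Itga6 on each array (points) with the mean and SD of each group (black). Foxp3 in CD25-CD49f+ cells averaged 8.25, between 4.74 in CD25-CD49f- cells and 9.85 in CD25+CD49f+ cells.

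All mice were labelled female, but 12 arrays showed Xist without Y-linked transcripts, 10 showed Y-linked transcripts without Xist, and 1 (CD25+CD49f- replicate 5) showed both. Xist is transcribed from the inactive X chromosome, and Eif2s3y, Kdm5d and Uty lie on the Y chromosome. The signal of an absent transcript differed between probe sets: on arrays without Y-linked transcripts Eif2s3y and Kdm5d read up to 4.07 and a further Uty probe set up to 5.62, and on arrays without Xist its probe set read up to 6.499. Differences and interactions that involve a group mean under 6.499 were taken as limited by background, so their sizes and order are those of the signals alone. Each group held both kinds: 4 Xist and 3 Y-linked arrays in each CD25- group, and 2 and 2 in each CD25+ group besides the array with both. Among arrays without Y-linked transcripts, Foxp3 differed by 3.40 between CD25-CD49f+ and CD25-CD49f- cells (limma adjusted p = 5.83e-08), and among Y-linked arrays by 3.66 (adjusted p = 4.59e-06), against 3.51 over all arrays. In the order of the comparisons that follow, arrays without Y-linked transcripts called 119, 1340, 493 and 1284 genes, with 370 for the interaction. The Y-linked arrays without Xist called 92, 1080, 264 and 1004 genes, with 242 for the interaction.

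The first comparison asked how CD49f divides CD25+ cells. Of 18194 genes, 332 were called between CD25+CD49f+ and CD25+CD49f- cells, 64 higher and 268 lower in CD25+CD49f+ cells, and 1335 had an unadjusted p under 0.05. Leaving out 1 array gave 32 to 94 higher genes, and arrays without Y-linked transcripts alone 3 of 119. By at least 1 on the log2 scale, 11 were higher and 95 lower. The largest increase was Itgb1 (1.74 ± 0.29, adjusted p = 4.73e-04), which codes the integrin beta 1 chain that pairs with CD49f. Among arrays without Y-linked transcripts the Itgb1 difference was 1.15 (adjusted p = 0.144), and among Y-linked arrays 1.61 (adjusted p = 0.0281). Gucy1a1, a guanylate cyclase subunit, Capn3, a calpain protease, and Npas4, a transcription factor, rose by 1.35, 1.21 and 1.17. Genes of mitosis also rose, with Ccnb2 (1.09 ± 0.20), Ube2c (1.08 ± 0.21), Kif20a (1.07 ± 0.26) and Birc5 (1.05 ± 0.19). The largest measured decreases were those of Klrb1b, a lectin-like receptor of the NK gene complex (-4.21 ± 0.10, adjusted p = 2.76e-20), Fam184b (-3.85), the kinase gene Mapk10 (-3.51), the potassium channel gene Kcnk1 (-3.45), Tmem176b (-3.34), Tmem176a (-3.24), Hebp1 (-3.16) and Abi3bp (-3.12). In CD25+CD49f+ cells Klrb1b (4.06), Fam184b (3.47), Mapk10 (2.66), Abi3bp (2.84), Kcnk1 (4.64) and Hebp1 (5.36) were among the genes in the range of absent transcripts, which leaves the order of their differences open. Foxp3 (0.06 ± 0.15, adjusted p = 0.999) and Il2ra (-0.08 ± 0.13, adjusted p = 0.999) were not called.

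Cell cycle genes had 11 higher, 0 lower and 29 uncalled members (27 higher and 0 lower adjusted over the list alone), with camera adjusted p = 2.71e-27, and 0.0195 with the estimated correlation of 0.366. Called members included Cdk1 (0.82), Birc5 (1.05) and Ccnb2 (1.09). Th17 genes had 0 higher, 8 lower and 4 uncalled members (0 higher and 9 lower adjusted over the list alone), with camera adjusted p = 2.62e-37. Called members included Tmem176a (-3.24), Tmem176b (-3.34), Il17re (-2.17) and Il1r1 (-2.06). Chemokine receptors had 0 higher, 4 lower and 16 uncalled members (1 higher and 5 lower adjusted over the list alone), with camera adjusted p = 1.01e-06. Called members included Ccr9 (-2.36), Ccr6 (-1.33) and Cxcr6 (-2.28). Effector and memory genes had 1 higher, 8 lower and 19 uncalled members (2 higher and 10 lower adjusted over the list alone), with camera adjusted p = 1.32e-08. Called members included Lgals3 (-2.49), Ccr6 (-1.33) and S100a4 (-1.27). Th1 genes had 0 higher, 5 lower and 10 uncalled members (0 higher and 5 lower adjusted over the list alone), with camera adjusted p = 1.18e-05. Called members included Il18rap (-0.92), Il18r1 (-0.60) and Runx3 (-0.80). Naive and lymphoid-homing genes had 0 higher, 6 lower and 11 uncalled members (1 higher and 6 lower adjusted over the list alone), with camera adjusted p = 1.01e-06. Called members included Ccr9 (-2.36), Pdlim4 (-1.09) and Il7r (-1.04). Treg suppressive effector genes had 2 higher, 5 lower and 15 uncalled members (3 higher and 8 lower adjusted over the list alone), with camera adjusted p = 0.00476 but adjusted p = 0.205 with an estimated correlation. Called members included Klrg1 (-1.95), Nt5e (0.95) and Itgae (-1.21). Of the Treg identity genes, 3 were higher and 2 lower (5 and 4 adjusted over the list alone), with Plagl1 (1.00) and Nt5e (0.95), which codes the ectoenzyme CD73, higher and Penk (-1.24) and Itgae (-1.21) lower.

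NK cell markers had 0 higher, 3 lower and 11 uncalled members (0 higher and 4 lower adjusted over the list alone), with camera adjusted p = 5.31e-05. Called members included Cd160 (-1.01), Fasl (-0.52) and Eomes (-0.75). Gamma delta and NKT cell markers had 0 higher, 3 lower and 4 uncalled members (0 higher and 3 lower adjusted over the list alone), with camera adjusted p = 1.32e-08. Called members included 5830411N06Rik (-1.36), Blk (-0.80) and Zbtb16 (-0.72). B cell markers had 0 higher, 5 lower and 14 uncalled members (0 higher and 5 lower adjusted over the list alone), with camera adjusted p = 0.0489 but adjusted p = 0.617 with an estimated correlation and 0.0583 without the 4 arrays that stood apart. Called members included H2-Aa (-1.70), Blk (-0.80) and H2-Ab1 (-1.54). CD8 T cell markers had 0 higher, 1 lower and 6 uncalled members (0 higher and 1 lower adjusted over the list alone), with camera adjusted p = 0.0489 but adjusted p = 0.0909 with an estimated correlation and 0.078 without the 4 arrays that stood apart. Called members included Eomes (-0.75). Platelet and megakaryocyte markers had 0 higher, 3 lower and 13 uncalled members (0 higher and 4 lower adjusted over the list alone), with camera adjusted p = 0.0244 but adjusted p = 0.425 with an estimated correlation and 0.353 without the 4 arrays that stood apart. Called members included Nrgn (-1.22), Itgb3 (-0.74) and F2rl2 (-1.01). Thymocyte markers had 0 higher, 1 lower and 8 uncalled members (0 higher and 1 lower adjusted over the list alone), with camera adjusted p = 0.0376 but adjusted p = 0.167 with an estimated correlation and 0.0878 without the 4 arrays that stood apart. Called members included Themis (-0.57). Erythroid markers had 1 higher, 0 lower and 10 uncalled members (3 higher and 0 lower adjusted over the list alone), with camera adjusted p = 5.48e-04 but adjusted p = 0.0532 with an estimated correlation. Called members included Rhd (0.40). With an estimated correlation 8 of the 14 called lists held, namely those for the cell cycle, Th17, Th1, chemokine receptors, effector and memory cells, naive cells, NK cells and gamma delta and NKT cells. Camera called no shift for Treg identity genes, integrin genes, laminin genes and other laminin receptors, Th2 genes, Tfh genes, TCR-induced early genes, IL-2 and STAT5 targets, interferon response genes, glycolysis genes, cholesterol biosynthesis genes, TNF receptor superfamily genes, plasma cell markers, myeloid and dendritic cell markers, neutrophil markers, stromal and endothelial markers, heat shock and dissociation stress genes and ribosomal protein genes (adjusted p from 0.0712 to 0.888). Without the 4 arrays that stood apart camera called laminin genes and other laminin receptors (adjusted p = 0.0338), Tfh genes (adjusted p = 0.0188), IL-2 and STAT5 targets (adjusted p = 0.0338) and cholesterol biosynthesis genes (adjusted p = 0.00182). With the brighter 9097 genes camera called ribosomal protein genes (adjusted p = 0.0495). Without CD25+CD49f- replicate 1 it called Treg identity genes. Myeloid and dendritic cell markers were called with the Actb covariate and in arrays without Y-linked transcripts. They were also called without CD25+CD49f- replicate 1 and without CD25+CD49f+ replicate 2 or 3. Neutrophil markers were called in Y-linked arrays without Xist. The median, mean and test direction differed in sign for integrin genes (median 0.00, mean 0.00, test downward), TCR-induced early genes (median -0.02, mean 0.02, test upward), interferon response genes (median -0.02, mean 0.02, test upward), B cell markers (median 0.05, mean -0.25, test downward), myeloid and dendritic cell markers (median 0.00, mean -0.21, test downward), neutrophil markers (median -0.02, mean 0.03, test upward) and platelet and megakaryocyte markers (median 0.03, mean -0.18, test downward).

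The next comparison asked what CD49f marks outside the CD25+ gate. Between CD25-CD49f+ and CD25-CD49f- cells 2443 genes were called, 1457 higher and 986 lower in CD25-CD49f+ cells. Foxp3 (3.51 ± 0.12, adjusted p = 3.31e-16), Ifng, which codes interferon gamma (3.51 ± 0.22), and Ctla4, which codes an inhibitory receptor of Treg and activated T cells (3.51 ± 0.14), had the largest measured increases. Depdc1a (3.36), Cep55 (3.05) and Pclaf (3.04), genes of dividing cells, also rose, as did Rgs1 (3.28) and the phosphatase gene Dusp4 (3.13). Foxp3 (4.74) and Depdc1a (3.91) lay in the range of absent transcripts in CD25-CD49f- cells. Il2ra rose by 1.42 (adjusted p = 1.85e-10) and Itgb1 by 2.13 (adjusted p = 1.31e-07). The largest decreases were Klra17 (-2.17), Pdlim4 (-2.17), Kmo (-2.09), Rnase6 (-2.06), Ccnd1 (-1.94), Itgax (-1.92), Tbc1d8 (-1.88) and Dnase1l3 (-1.86). Itgax is also on the myeloid and dendritic cell list, which averaged 7.61 in CD25-CD49f- cells and 7.02 in CD25-CD49f+ cells. A share of such cells in the CD25-CD49f- gate was not tested as a source of these decreases.

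Cell cycle genes had 38 higher, 0 lower and 2 uncalled members (38 higher and 0 lower adjusted over the list alone), with camera adjusted p = 1.26e-66, and 2.62e-04 with the estimated correlation of 0.366. Called members included Cdk1 (2.54), Birc5 (3.02) and Ccnb2 (2.95). Treg identity genes had 21 higher, 0 lower and 2 uncalled members (21 higher and 0 lower adjusted over the list alone), with camera adjusted p = 9.97e-41, and 1.07e-04 with the estimated correlation of 0.228. Called members included Foxp3 (3.51), Ikzf2 (2.63) and Ctla4 (3.51). Effector and memory genes had 22 higher, 0 lower and 6 uncalled members (22 higher and 0 lower adjusted over the list alone), with camera adjusted p = 8.72e-33. Called members included Anxa2 (1.87), S100a6 (2.06) and Cxcr3 (1.67). TCR-induced early genes had 22 higher, 0 lower and 3 uncalled members (23 higher and 0 lower adjusted over the list alone), with camera adjusted p = 1.72e-22. Called members included Tnfaip3 (2.32), Nr4a1 (1.40) and Fosb (2.14). Treg suppressive effector genes had 15 higher, 1 lower and 6 uncalled members (15 higher and 1 lower adjusted over the list alone), with camera adjusted p = 9.25e-19. Called members included Ctla4 (3.51), Gzmb (1.73) and Nt5e (2.01). Tfh genes had 13 higher, 1 lower and 3 uncalled members (13 higher and 1 lower adjusted over the list alone), with camera adjusted p = 2.49e-12. Called members included Cd200 (1.79), Icos (1.58) and Pdcd1 (1.45). Th1 genes had 10 higher, 0 lower and 5 uncalled members (10 higher and 2 lower adjusted over the list alone), with camera adjusted p = 4.39e-10. Called members included Cxcr3 (1.67), Ifng (3.51) and Tbx21 (1.26). IL-2 and STAT5 targets had 11 higher, 3 lower and 6 uncalled members (12 higher and 4 lower adjusted over the list alone), with camera adjusted p = 2.31e-06. Called members included Il2rb (1.90), Gzmb (1.73) and Socs2 (1.49). Naive and lymphoid-homing genes had 0 higher, 11 lower and 6 uncalled members (0 higher and 14 lower adjusted over the list alone), with camera adjusted p = 1.12e-14. Called members included Pdlim4 (-2.17), Bach2 (-1.17) and Igfbp4 (-1.36).

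Th2 genes had 5 higher, 1 lower and 5 uncalled members (7 higher and 1 lower adjusted over the list alone), with camera adjusted p = 0.00167 but adjusted p = 0.108 with the brighter 9097 genes. Called members included Nfil3 (1.53), Gata3 (0.94) and Il4ra (-0.68). Th17 genes had 4 higher, 2 lower and 6 uncalled members (4 higher and 2 lower adjusted over the list alone), with camera adjusted p = 0.0085 but adjusted p = 0.0996 with the brighter 9097 genes. Called members included Rora (1.52), Ccr6 (1.25) and Ahr (1.07). Chemokine receptors had 7 higher, 3 lower and 10 uncalled members (8 higher and 3 lower adjusted over the list alone), with camera adjusted p = 0.00211 but adjusted p = 0.0649 with the brighter 9097 genes. Called members included Cxcr3 (1.67), Ccr6 (1.25) and Ccr7 (-0.98). Glycolysis genes had 6 higher, 0 lower and 14 uncalled members (6 higher and 0 lower adjusted over the list alone), with camera adjusted p = 0.00167 but adjusted p = 0.155 with an estimated correlation. Called members included Pgk1 (0.51), Tpi1 (0.57) and Slc2a3 (0.53). Heat shock and dissociation stress genes had 8 higher, 0 lower and 9 uncalled members (8 higher and 0 lower adjusted over the list alone), with camera adjusted p = 5.98e-05 but adjusted p = 0.0719 with an estimated correlation. Called members included Jun (1.95), Egr1 (0.76) and Atf3 (0.64). Jun and Egr1 are also on the list of TCR-induced early genes, and a response to T cell receptor signals and one to handling were not told apart. Ribosomal protein genes had 0 higher, 3 lower and 27 uncalled members (0 higher and 3 lower adjusted over the list alone), with camera adjusted p = 0.00641 but adjusted p = 0.252 with an estimated correlation. Called members included Rpl12 (-0.78) and Rpl8 (-0.25). Interferon response genes had 4 higher, 5 lower and 21 uncalled members (4 higher and 5 lower adjusted over the list alone), with camera adjusted p = 0.35. Called members included Gbp3 (1.88) and Oas1a (0.52). Integrin genes had 5 higher, 2 lower and 16 uncalled members (5 higher and 3 lower adjusted over the list alone), with camera adjusted p = 0.185. Called members included Itgae (2.36), Itgb1 (2.13) and Itgax (-1.92). Laminin genes and other laminin receptors had 2 higher, 1 lower and 14 uncalled members (2 higher and 1 lower adjusted over the list alone), with camera adjusted p = 0.984. Called members included Itgb1 (2.13) and Dag1 (-0.44).

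Myeloid and dendritic cell markers had 0 higher, 10 lower and 10 uncalled members (0 higher and 11 lower adjusted over the list alone), with camera adjusted p = 1.2e-05 but adjusted p = 0.192 with an estimated correlation. Called members included Siglech (-1.36), Itgax (-1.92), Mpeg1 (-1.40) and Tyrobp (-1.44). B cell markers had 0 higher, 6 lower and 13 uncalled members (0 higher and 6 lower adjusted over the list alone), with camera adjusted p = 0.0142 but adjusted p = 0.417 with an estimated correlation. Called members included H2-Eb1 (-1.85), Cd74 (-1.73) and H2-Aa (-1.48). Gamma delta and NKT cell markers had 3 higher, 0 lower and 4 uncalled members (3 higher and 0 lower adjusted over the list alone), with camera adjusted p = 0.00168. Called members included 5830411N06Rik (0.76), Maf (2.27) and Zbtb16 (0.58). Thymocyte markers had 0 higher, 1 lower and 8 uncalled members (0 higher and 6 lower adjusted over the list alone), with camera adjusted p = 0.0105 but adjusted p = 0.0754 with an estimated correlation and 0.183 with the brighter 9097 genes. Called members included Dntt (-0.49). Plasma cell markers had 2 higher, 0 lower and 7 uncalled members (2 higher and 0 lower adjusted over the list alone), with camera adjusted p = 0.187. Called members included Irf4 (1.43) and Prdm1 (0.49). With an estimated correlation 13 of the 19 called lists held. Camera called no shift for integrin genes, laminin genes and other laminin receptors, interferon response genes, cholesterol biosynthesis genes, TNF receptor superfamily genes, plasma cell markers, neutrophil markers, NK cell markers, CD8 T cell markers, platelet and megakaryocyte markers, erythroid markers and stromal and endothelial markers (adjusted p from 0.0797 to 0.984). With the brighter 9097 genes camera called CD8 T cell markers (adjusted p = 0.0363). The median, mean and test direction differed in sign for laminin genes and other laminin receptors (median -0.03, mean 0.11, test upward), TNF receptor superfamily genes (median -0.01, mean 0.17, test upward) and NK cell markers (median 0.03, mean -0.13, test downward).

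CD25 within CD49f+ cells was compared next, to see what separates the CD25+ and CD25- members of the CD49f+ gate. Between CD25+CD49f+ and CD25-CD49f+ cells 1040 genes were called, 511 higher and 529 lower in CD25+CD49f+ cells. Il2ra (2.76 ± 0.12, adjusted p = 9.47e-14), the netrin gene Ntn4 (2.67), Gpr83, a receptor gene of Treg cells (2.55), Rragd (2.53), the calcium channel gene Ryr2 (2.37), Sh3bgrl2 (2.30), Itih5 (2.23) and Plagl1 (2.19) rose most. Dapl1 (-2.74), Esm1 (-2.70), Pdlim4 (-2.64), Vipr1 (-2.45), Pde3b (-2.44), the chemokine receptor gene Cxcr6 (-2.26), Emp1 (-2.10) and App (-2.00) fell most. Foxp3 was higher by 1.60 (adjusted p = 1.35e-08) and Itga6 by 0.45 (adjusted p = 0.00288).

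Treg identity genes had 22 higher, 0 lower and 1 uncalled members (22 higher and 0 lower adjusted over the list alone), with camera adjusted p = 1.56e-52, and 3.6e-05 with an estimated correlation. Called members included Gpr83 (2.55), Il2ra (2.76) and Plagl1 (2.19). IL-2 and STAT5 targets had 12 higher, 0 lower and 8 uncalled members (15 higher and 0 lower adjusted over the list alone), with camera adjusted p = 7.4e-24. Called members included Il2ra (2.76), Socs2 (1.86) and Lta (1.35). TNF receptor superfamily genes had 5 higher, 0 lower and 16 uncalled members (5 higher and 0 lower adjusted over the list alone), with camera adjusted p = 1.09e-05. Called members included Tnfrsf4 (1.30), Tnfrsf9 (1.44) and Tnfrsf18 (0.92). Cell cycle genes had 0 higher, 23 lower and 17 uncalled members (0 higher and 28 lower adjusted over the list alone), with camera adjusted p = 8.06e-31, and 0.0072 with an estimated correlation. Called members included Plk1 (-1.10), Ube2c (-1.45) and Cdc20 (-0.97). Effector and memory genes had 0 higher, 15 lower and 13 uncalled members (2 higher and 17 lower adjusted over the list alone), with camera adjusted p = 1.23e-23. Called members included Cxcr3 (-1.35), Anxa2 (-1.08) and S100a6 (-1.12). Th1 genes had 0 higher, 7 lower and 8 uncalled members (0 higher and 10 lower adjusted over the list alone), with camera adjusted p = 2.12e-12. Called members included Cxcr3 (-1.35), Tbx21 (-1.28) and Il18rap (-1.05). Naive and lymphoid-homing genes had 1 higher, 7 lower and 9 uncalled members (2 higher and 10 lower adjusted over the list alone), with camera adjusted p = 2.38e-07. Called members included Dapl1 (-2.74), Pdlim4 (-2.64) and Igfbp4 (-1.04). Chemokine receptors had 0 higher, 5 lower and 15 uncalled members (2 higher and 8 lower adjusted over the list alone), with camera adjusted p = 2.46e-06. Called members included Cxcr3 (-1.35), Ccr10 (-1.14) and Ccr2 (-0.75). Treg suppressive effector genes had 10 higher, 1 lower and 11 uncalled members (11 higher and 3 lower adjusted over the list alone), with camera adjusted p = 2.0e-04 but adjusted p = 0.0663 with an estimated correlation. Called members included Il1r2 (0.80), Lgals1 (-0.68) and Ctla4 (0.93). Tfh genes had 2 higher, 5 lower and 10 uncalled members (2 higher and 6 lower adjusted over the list alone), with camera adjusted p = 0.00446 but adjusted p = 0.0879 with an estimated correlation and 0.376 with the brighter 9097 genes. Called members included Il21 (-1.29), Tox2 (-0.99) and Il4 (-0.67).

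Th17 genes had 0 higher, 3 lower and 9 uncalled members (1 higher and 3 lower adjusted over the list alone), with camera adjusted p = 0.015 but adjusted p = 0.232 with the brighter 9097 genes. Called members included Il21 (-1.29) and Rora (-0.62). Integrin genes had 2 higher, 2 lower and 19 uncalled members (2 higher and 4 lower adjusted over the list alone), with camera adjusted p = 0.0328 but adjusted p = 0.0553 without the 4 arrays that stood apart and 0.387 with the brighter 9097 genes. Called members included Itgb3 (-1.18) and Itgae (0.95). Glycolysis genes had 4 higher, 0 lower and 16 uncalled members (5 higher and 0 lower adjusted over the list alone), with camera adjusted p = 0.0304 but adjusted p = 0.353 with an estimated correlation and 0.205 with the brighter 9097 genes. Called members included Eno3 (1.90) and Eno2 (0.86). Cholesterol biosynthesis genes had 0 higher, 0 lower and 20 uncalled members (0 higher and 0 lower adjusted over the list alone), with camera adjusted p = 0.0258 but adjusted p = 0.3 with an estimated correlation and 0.111 with the brighter 9097 genes. Neutrophil markers had 0 higher, 2 lower and 10 uncalled members (0 higher and 9 lower adjusted over the list alone), with camera adjusted p = 3.69e-08. Called members included Mpo (-1.46) and S100a9 (-0.89). NK cell markers had 0 higher, 3 lower and 11 uncalled members (0 higher and 3 lower adjusted over the list alone), with camera adjusted p = 7.38e-05. Called members included Fasl (-1.40) and Klrd1 (-1.24). CD8 T cell markers had 0 higher, 2 lower and 5 uncalled members (0 higher and 3 lower adjusted over the list alone), with camera adjusted p = 1.82e-04. Called members included Gzmk (-1.77) and Nkg7 (-0.53). Gamma delta and NKT cell markers had 0 higher, 2 lower and 5 uncalled members (0 higher and 2 lower adjusted over the list alone), with camera adjusted p = 0.00125. Called members included Zbtb16 (-0.81) and 5830411N06Rik (-0.62). Myeloid and dendritic cell markers had 0 higher, 1 lower and 19 uncalled members (0 higher and 1 lower adjusted over the list alone), with camera adjusted p = 0.00502 but adjusted p = 0.423 with an estimated correlation and 0.0799 with the brighter 9097 genes. Called members included Fcgr3 (-0.77).

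Erythroid markers had 0 higher, 0 lower and 11 uncalled members (0 higher and 4 lower adjusted over the list alone), with camera adjusted p = 0.00605 but adjusted p = 0.0879 with an estimated correlation. Thymocyte markers had 0 higher, 2 lower and 7 uncalled members (0 higher and 2 lower adjusted over the list alone), with camera adjusted p = 0.0171 but adjusted p = 0.0879 with an estimated correlation. Called members included Themis (-1.52) and Cd4 (-0.41). With an estimated correlation 14 of the 21 called lists held. Camera called no shift for laminin genes and other laminin receptors, Th2 genes, TCR-induced early genes, interferon response genes, B cell markers, plasma cell markers, platelet and megakaryocyte markers, stromal and endothelial markers, heat shock and dissociation stress genes and ribosomal protein genes (adjusted p from 0.121 to 0.985). With the brighter 9097 genes camera called Th2 genes (adjusted p = 0.0411) and TCR-induced early genes (adjusted p = 0.0396). The median, mean and test direction differed in sign for laminin genes and other laminin receptors (median -0.00, mean -0.02, test upward), Th2 genes (median -0.06, mean 0.04, test downward) and heat shock and dissociation stress genes (median 0.02, mean -0.08, test downward).

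The same question was asked of CD25 within CD49f- cells. Between CD25+CD49f- and CD25-CD49f- cells 2551 genes were called, 1699 higher and 852 lower in CD25+CD49f- cells. Foxp3 (5.05 ± 0.13, adjusted p = 1.26e-19), the enkephalin precursor gene Penk (4.59), Itgae, which codes CD103 (4.52), Ntn4 (4.35), Il2ra (4.27 ± 0.12, adjusted p = 2.65e-19), Dusp4 (4.12), Ctla4 (4.08) and Rgs1 (4.05) rose most. Pdlim4 (-3.72), Vipr1 (-3.28), Dapl1 (-3.17), Klrd1 (-2.56), Lrrc75b (-2.44), Itgax (-2.42), Sash1 (-2.38) and Cnga1 (-2.38) fell most.

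Treg identity genes had 23 higher, 0 lower and 0 uncalled members (23 higher and 0 lower adjusted over the list alone), with camera adjusted p = 1.1e-60, and 6.39e-06 with an estimated correlation. Called members included Foxp3 (5.05), Il2ra (4.27) and Gpr83 (3.35). Treg suppressive effector genes had 18 higher, 1 lower and 3 uncalled members (18 higher and 1 lower adjusted over the list alone), with camera adjusted p = 1.6e-23. Called members included Klrg1 (3.36), Ctla4 (4.08) and Itgae (4.52). Th17 genes had 10 higher, 0 lower and 2 uncalled members (10 higher and 0 lower adjusted over the list alone), with camera adjusted p = 2.13e-19. Called members included Tmem176a (2.75), Tmem176b (2.33) and Il17re (2.12). IL-2 and STAT5 targets had 13 higher, 2 lower and 5 uncalled members (14 higher and 2 lower adjusted over the list alone), with camera adjusted p = 1.87e-18. Called members included Il2ra (4.27), Il2rb (3.01) and Socs2 (2.99). Effector and memory genes had 18 higher, 0 lower and 10 uncalled members (19 higher and 0 lower adjusted over the list alone), with camera adjusted p = 1.49e-14. Called members included Lgals3 (2.72), Bhlhe40 (1.89) and S100a6 (1.47). TCR-induced early genes had 19 higher, 0 lower and 6 uncalled members (20 higher and 0 lower adjusted over the list alone), with camera adjusted p = 9.27e-18. Called members included Nr4a3 (1.38), Nr4a1 (1.66) and Dusp5 (1.35). Cell cycle genes had 23 higher, 0 lower and 17 uncalled members (29 higher and 0 lower adjusted over the list alone), with camera adjusted p = 5.29e-13 but adjusted p = 0.0752 with an estimated correlation. Called members included Mcm5 (0.97), Tk1 (1.17) and Rrm2 (1.54). Naive and lymphoid-homing genes had 2 higher, 11 lower and 4 uncalled members (2 higher and 13 lower adjusted over the list alone), with camera adjusted p = 6.04e-13. Called members included Pdlim4 (-3.72), Dapl1 (-3.17) and Lef1 (-1.17). TNF receptor superfamily genes had 7 higher, 3 lower and 11 uncalled members (7 higher and 3 lower adjusted over the list alone), with camera adjusted p = 0.00303 but adjusted p = 0.0601 with an estimated correlation. Called members included Tnfrsf4 (2.78), Tnfrsf9 (2.70) and Tnfrsf18 (1.40). Tfh genes had 10 higher, 1 lower and 6 uncalled members (10 higher and 1 lower adjusted over the list alone), with camera adjusted p = 1.18e-06. Called members included Cd200 (2.14), Icos (1.61) and Izumo1r (1.83).

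Th1 genes had 7 higher, 2 lower and 6 uncalled members (8 higher and 2 lower adjusted over the list alone), with camera adjusted p = 5.02e-04. Called members included Il18r1 (1.07) and Ifng (2.50). Th2 genes had 4 higher, 0 lower and 7 uncalled members (4 higher and 0 lower adjusted over the list alone), with camera adjusted p = 0.00413. Called members included Nfil3 (1.96) and Gata3 (1.04). Glycolysis genes had 7 higher, 1 lower and 12 uncalled members (9 higher and 2 lower adjusted over the list alone), with camera adjusted p = 5.42e-05 but adjusted p = 0.0752 with an estimated correlation. Called members included Eno3 (1.63) and Eno2 (1.03). Gamma delta and NKT cell markers had 4 higher, 0 lower and 3 uncalled members (5 higher and 0 lower adjusted over the list alone), with camera adjusted p = 5.42e-05. Called members included Blk (0.80) and Maf (2.21). Myeloid and dendritic cell markers had 2 higher, 9 lower and 9 uncalled members (2 higher and 10 lower adjusted over the list alone), with camera adjusted p = 1.58e-05 but adjusted p = 0.186 with an estimated correlation. Called members included Itgax (-2.42) and Mpeg1 (-1.58). Neutrophil markers had 0 higher, 2 lower and 10 uncalled members (0 higher and 2 lower adjusted over the list alone), with camera adjusted p = 0.00104 but adjusted p = 0.186 with an estimated correlation. Called members included Mpo (-1.76) and Elane (-0.64). Heat shock and dissociation stress genes had 7 higher, 0 lower and 10 uncalled members (9 higher and 1 lower adjusted over the list alone), with camera adjusted p = 4.25e-04 but adjusted p = 0.102 with an estimated correlation. Called members included Fos (2.24) and Jun (2.12). Ribosomal protein genes had 0 higher, 2 lower and 28 uncalled members (0 higher and 2 lower adjusted over the list alone), with camera adjusted p = 0.0155 but adjusted p = 0.307 with an estimated correlation and 0.0698 without the 4 arrays that stood apart. Called members included Rpl12 (-0.54) and Rpl8 (-0.27).

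B cell markers had 1 higher, 3 lower and 15 uncalled members (1 higher and 3 lower adjusted over the list alone), with camera adjusted p = 0.0248 but adjusted p = 0.474 with an estimated correlation and 0.0779 with the brighter 9097 genes. Called members included Blk (0.80) and Spib (-1.55). Erythroid markers had 0 higher, 3 lower and 8 uncalled members (0 higher and 4 lower adjusted over the list alone), with camera adjusted p = 0.00303 but adjusted p = 0.0752 with an estimated correlation and 0.0536 with the brighter 9097 genes. Called members included Car1 (-1.58) and Ermap (-0.64). Stromal and endothelial markers had 1 higher, 2 lower and 13 uncalled members (1 higher and 2 lower adjusted over the list alone), with camera adjusted p = 0.0308 but adjusted p = 0.193 with an estimated correlation, 0.0521 without the 4 arrays that stood apart and 0.358 with the brighter 9097 genes. Called members included Cdh5 (-0.75) and Vwf (-0.46). Thymocyte markers had 0 higher, 3 lower and 6 uncalled members (0 higher and 3 lower adjusted over the list alone), with camera adjusted p = 0.00331 but adjusted p = 0.051 with an estimated correlation. Called members included Themis (-1.17) and Dntt (-0.63). With an estimated correlation 11 of the 22 called lists held. Camera called no shift for integrin genes, laminin genes and other laminin receptors, chemokine receptors, interferon response genes, cholesterol biosynthesis genes, plasma cell markers, NK cell markers, CD8 T cell markers and platelet and megakaryocyte markers (adjusted p from 0.0504 to 0.868). Chemokine receptors were called with Y-linked transcripts or the Actb difference as a covariate, and within arrays without Y-linked transcripts and Y-linked arrays without Xist. Many fits that left out 1 array called them too, and fry called them and plasma cell markers. The median, mean and test direction differed in sign for integrin genes (median -0.08, mean 0.11, test downward) and platelet and megakaryocyte markers (median -0.00, mean 0.02, test downward).

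**Figure D2:**
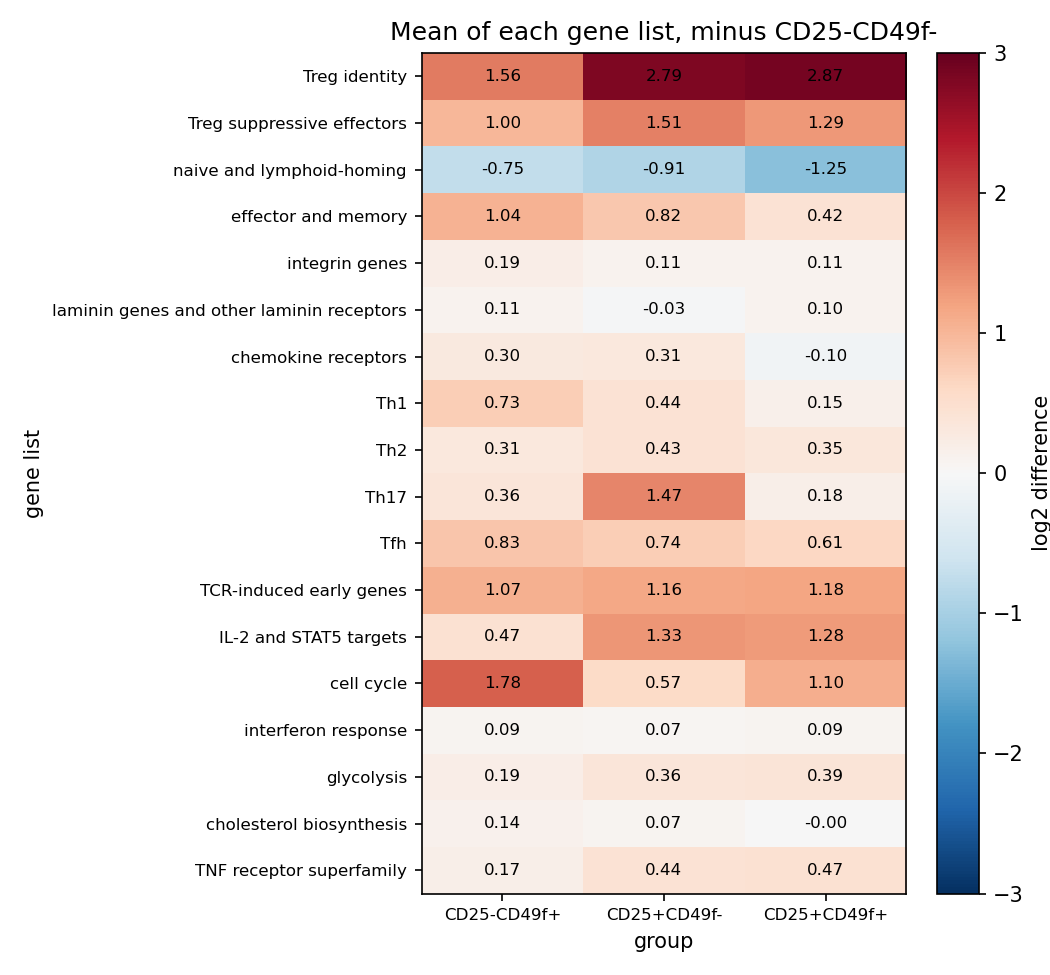
Mean log2 expression of each of 18 gene lists in 3 groups, each minus the mean in CD25-CD49f- cells (color scale and numbers in log2 units). The cell cycle list was 1.78 higher in CD25-CD49f+ cells, 0.57 higher in CD25+CD49f- cells and 1.10 higher in CD25+CD49f+ cells, and the Th17 list was 1.47 higher in CD25+CD49f- cells.

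The interaction tested whether the CD49f difference differed between CD25+ and CD25- cells, and was taken as the difference within CD25+ cells minus that within CD25- cells. It was called for 966 genes, 179 with a higher and 787 with a lower difference in CD25+ cells. The smallest p-values were those of Arnt2, a transcription factor (-3.85 ± 0.11, adjusted p = 1.65e-18), Klrb1b (-3.97 ± 0.12, adjusted p = 2.01e-17), Kcnk1 (-3.42), Pxdc1 (-3.18), Tmem176a (-2.89), Klrg1, an inhibitory receptor (-3.11), Lgals3, which codes galectin 3 (-3.74), and Upp1 (-2.59). The size of the Klrb1b interaction was not fixed, since the gene lay in the range of absent transcripts in the groups other than CD25+CD49f- (4.23, 3.98 and 4.06). The same held for Arnt2 (4.71, 5.45 and 5.40), Kcnk1 (4.61, 4.58 and 4.64), Pxdc1 (5.95, 6.05 and 5.92) and Upp1 (4.91, 5.01 and 5.15). Klrg1 (6.488), Foxp3 (4.74) and Il2ra (5.42) lay in that range in CD25-CD49f- cells. The interaction was -3.46 ± 0.19 (adjusted p = 2.83e-12) for Foxp3, -1.51 ± 0.17 (adjusted p = 9.57e-07) for Il2ra and 0.60 ± 0.13 (adjusted p = 0.00412) for Itga6.

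Treg identity genes had 0 higher, 17 lower and 6 uncalled members (1 higher and 21 lower adjusted over the list alone), with camera adjusted p = 4.81e-39. Cell cycle genes had 0 higher, 32 lower and 8 uncalled members (0 higher and 36 lower adjusted over the list alone), with camera adjusted p = 4.78e-45. Effector and memory genes had 0 higher, 22 lower and 6 uncalled members (0 higher and 23 lower adjusted over the list alone), with camera adjusted p = 1.4e-43. Th17 genes had 0 higher, 9 lower and 3 uncalled members (0 higher and 10 lower adjusted over the list alone), with camera adjusted p = 1.01e-29. TCR-induced early genes had 0 higher, 16 lower and 9 uncalled members (1 higher and 20 lower adjusted over the list alone), with camera adjusted p = 9.59e-19. Treg suppressive effector genes had 1 higher, 12 lower and 9 uncalled members (1 higher and 16 lower adjusted over the list alone), with camera adjusted p = 1.33e-22. Naive and lymphoid-homing genes had 5 higher, 1 lower and 11 uncalled members (11 higher and 2 lower adjusted over the list alone), with camera adjusted p = 6.97e-06. Heat shock and dissociation stress genes had 0 higher, 4 lower and 13 uncalled members (0 higher and 6 lower adjusted over the list alone), with camera adjusted p = 2.41e-04 but adjusted p = 0.1 with an estimated correlation. Ribosomal protein genes had 1 higher, 0 lower and 29 uncalled members (1 higher and 0 lower adjusted over the list alone), with camera adjusted p = 5.46e-04 but adjusted p = 0.168 with an estimated correlation. Myeloid and dendritic cell markers had 3 higher, 2 lower and 15 uncalled members (5 higher and 2 lower adjusted over the list alone), with camera adjusted p = 0.0179 but adjusted p = 0.51 with an estimated correlation.

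Glycolysis genes had 0 higher, 1 lower and 19 uncalled members (0 higher and 1 lower adjusted over the list alone), with camera adjusted p = 0.0207 but adjusted p = 0.319 with an estimated correlation and 0.205 with the brighter 9097 genes. Cholesterol biosynthesis genes had 0 higher, 0 lower and 20 uncalled members (0 higher and 0 lower adjusted over the list alone), with camera adjusted p = 0.0425 but adjusted p = 0.339 with an estimated correlation and 0.209 with the brighter 9097 genes. The chemokine receptors and the Th1, Th2, Tfh, IL-2 and STAT5, CD8 T cell and gamma delta and NKT lists also shifted down (camera adjusted p from 1.34e-16 to 0.0112) and held with an estimated correlation, while the Th2 list was not called with the brighter 9097 genes (adjusted p = 0.116). With an estimated correlation 14 of the 19 called lists held. Camera called no shift for integrin genes, laminin genes and other laminin receptors, interferon response genes, TNF receptor superfamily genes, B cell markers, plasma cell markers, neutrophil markers, NK cell markers, platelet and megakaryocyte markers, erythroid markers, stromal and endothelial markers and thymocyte markers (adjusted p from 0.0598 to 0.677). With the brighter 9097 genes camera called TNF receptor superfamily genes (adjusted p = 0.0465). NK cell markers were called by fry, with Y-linked transcripts as a covariate and in several fits that left out 1 array. Fry also called integrin genes, and camera called B cell markers in Y-linked arrays without Xist. The median, mean and test direction differed in sign for laminin genes and other laminin receptors (median -0.00, mean 0.01, test upward), TNF receptor superfamily genes (median 0.01, mean -0.14, test downward), plasma cell markers (median 0.11, mean -0.16, test downward) and platelet and megakaryocyte markers (median 0.01, mean -0.08, test downward).

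Across 18194 genes, which are not independent replicates, the CD49f differences in CD25+ and CD25- cells, which share no array, correlated with Pearson r = 0.226 and Spearman rho = 0.172. Of the 64 genes higher in CD25+CD49f+ than in CD25+CD49f- cells, 58 were also higher in CD25-CD49f+ than in CD25-CD49f- cells, against 5.13 for independent lists. Of the 268 lower genes, 70 were also lower (14.5 for independent lists) and 54 were higher (21.5). The CD25 differences in CD49f+ and CD49f- cells, from arrays that also do not overlap, correlated with r = 0.438 and rho = 0.264. Of the 511 genes higher with CD25 in CD49f+ cells, 374 were also higher in CD49f- cells (47.7 for independent lists), and of the 529 lower genes 205 were also lower (24.8) and 83 were higher (49.4).

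**Figure D3:**
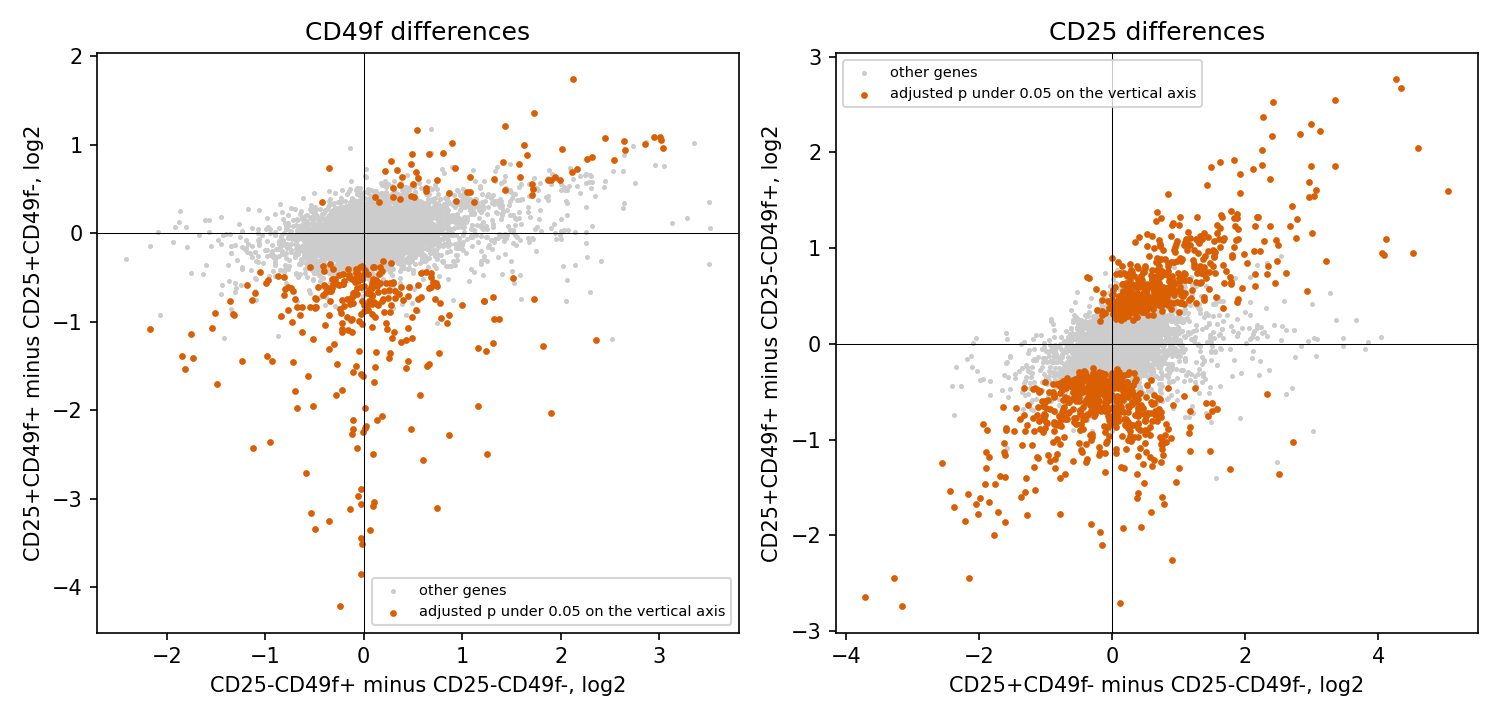
Log2 differences of each gene with CD49f (left, CD25- cells across, CD25+ cells up) and with CD25 (right, CD49f- cells across, CD49f+ cells up), with genes called on the vertical axis in orange. The correlations were 0.226 and 0.438.

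A set of 4 arrays stood apart from their group by the median correlation with its other arrays, CD25-CD49f- replicates 7 (0.967) and 1 (0.982), CD25-CD49f+ replicate 1 (0.981) and CD25+CD49f- replicate 5 (0.975). The Actb control probe sets differed between the 3' and 5' ends by 4.83 in CD25+CD49f- replicate 5 and 2.70 in CD25-CD49f- replicate 1, against 1.22 to 2.09 in the other arrays.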

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

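The splits of the arrays were planned, while the tests of the Treg genes in CD25-CD49f+ cells, of the genes lower in CD25+CD49f+ cells and of the Itga6 transcript were chosen, and their bounds set, only after the results were seen.

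Each of the 5 counts of called genes was set against 99 other splits of the same arrays, which were drawn at random from the groups compared, with the real split as number 100. In CD25+ cells 1 of the 100 splits, the real one, called as many genes with CD49f (332, highest other split 151). In CD25- cells it was again 1 of 100 (2443, highest other 707). For CD25 it was 1 of 100 in CD49f+ cells (1040, highest other 180) and 1 of 100 in CD49f- cells (2551, highest other 1378). For the interaction 1 of 100 splits reached 966, with 109 as the highest other. There the CD49f labels were redrawn within CD25+ and within CD25- arrays, which removes the CD49f differences together with their interaction. These splits therefore cannot decide whether chance gives the interaction count when CD49f differences are present. Chance is an unlikely source of the counts of the pairwise comparisons, but 1 of 100 is the smallest value that this number of splits could give.

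A sample far from the others of its group was looked for in 244 sets of values, comprising 4 quality measures, the mean of each list, the probe sets of Il2ra, Itga6 and Foxp3, and genes named for the first comparison and the interaction. It was found in 25 sets, and chance gives about 1 in 20, or 12.2. The median correlation with the own group was low for CD25-CD49f- replicate 7 (0.967), CD25-CD49f+ replicate 1 (0.981) and CD25+CD49f- replicate 5 (0.975). The Actb 3' minus 5' difference was high in CD25+CD49f- replicate 5 (4.83), and that of Gapdh in CD25-CD49f- replicate 1 (3.02). CD25+CD49f- replicate 5 had the largest Gapdh difference of all arrays (3.97), which the rule did not flag within its group. CD25+CD49f- replicate 5 was low for effector and memory genes (9.81), Th17 genes (7.92), IL-2 and STAT5 targets (8.97) and Arnt2 (8.25). CD25-CD49f+ replicate 1 was low for Th17 genes (6.87), Tfh genes (7.74), plasma cell markers (7.50), the further Itga6 probe set (6.90) and Itgb1 (10.24), and high for ribosomal proteins (12.57). CD25-CD49f- replicate 7 was high for the TNF receptor superfamily (6.90) and low for gamma delta and NKT cell markers (6.02) and ribosomal proteins (12.57). CD25-CD49f- replicate 1 was low for CD8 T cell markers (6.33) and high for Klrg1 (6.97). The remaining far values were chemokine receptors in CD25-CD49f+ replicate 2 (7.05), Mapk10 in CD25-CD49f+ replicate 6 (2.44), Pxdc1 in CD25-CD49f- replicate 5 (5.74), Gucy1a1 in CD25+CD49f+ replicate 2 (7.89) and Kcnk1 in CD25+CD49f+ replicate 1 (4.77).

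The CD49f difference differed between CD25+ and CD25- cells, by limma's interaction term, for 966 genes. Among named genes the interaction was -3.85 for Arnt2, -3.97 for Klrb1b, -3.42 for Kcnk1, -3.18 for Pxdc1, -2.89 for Tmem176a, -3.11 for Klrg1, -3.74 for Lgals3, -2.59 for Upp1, -3.46 for Foxp3, -1.51 for Il2ra and 0.60 for Itga6. Arnt2, Klrb1b, Kcnk1, Pxdc1 and Upp1 lay near background in 3 of the 4 groups. Klrg1, Foxp3 and Il2ra lay in that range in CD25-CD49f- cells, so the sizes of all these interactions are not fixed. Of 19 lists with a called interaction 16 shifted down and 3 up. The mean interaction was -1.65 for Th17 genes, -1.48 for Treg identity genes, -1.43 for effector and memory genes, -1.26 for cell cycle genes, -1.21 for Treg suppressive effector genes, -1.06 for gamma delta and NKT cell markers, -1.05 for TCR-induced early genes, -1.02 for Th1 genes, -0.96 for Tfh genes. It was -0.74 for heat shock and dissociation stress genes, -0.71 for chemokine receptors, -0.53 for IL-2 and STAT5 targets, -0.41 for CD8 T cell markers, -0.39 for Th2 genes, -0.21 for cholesterol biosynthesis genes, -0.16 for glycolysis genes, 0.13 for ribosomal protein genes, 0.38 for myeloid and dendritic cell markers and 0.41 for naive and lymphoid-homing genes.

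CD25-CD49f+ cells carried Treg genes although they were sorted as CD25-. Carry-over of CD25+CD49f+ cells with the mean Il2ra level of their gate would bring Foxp3 and Il2ra at a like share. Il2ra codes the sort marker CD25, so carried-over cells could be those with less of it. On the linear scale the lowest Foxp3 share of a CD25-CD49f+ array, 0.218 of the way from CD25-CD49f- to CD25+CD49f+ cells, lay above the highest Il2ra share, 0.126. Shares were read for the 22 Treg identity members, Il2ra included, that were at least 1 log2 unit higher in CD25+CD49f+ than in CD25-CD49f- cells. Of these, 16 members other than Il2ra, Foxp3 among them, lay above 0.126 in every array. Swap70, Plagl1 and Penk overlapped the Il2ra shares, and Gpr83 (median 0.0413) and Gpr34 (-0.198) lay under the Il2ra median of 0.103. These shares argue against carry-over of CD25+CD49f+ cells with the mean Il2ra level as the whole source. They cannot decide about carried-over cells with less CD25, which would give a lower Il2ra share too. Carry-over of CD25+CD49f- cells is argued against by 62 genes, chosen without the CD25-CD49f+ arrays. They were called higher by at least 1 on the log2 scale in CD25+CD49f- than in both CD25-CD49f- and CD25+CD49f+ cells. Their median share in the CD25-CD49f+ arrays was 0.01. Under the 3 other scalings the lowest Foxp3 difference was 3.50. The values scaled had already been normalized by RMA, so this cannot decide whether that normalization was a cause. A Treg population with little CD25 within the CD25- gate may be the source, as a hypothesis, and a smaller share of carried-over cells stays open. Array signals compress low levels, which limits how exactly such shares can be read.

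The 95 genes lower by at least 1 in CD25+CD49f+ than in CD25+CD49f- cells form another pattern. Carry-over of CD25- cells into the CD25+CD49f- gate is argued against for 60 of them, whose lowest CD25+CD49f- array lay above the highest CD25- array, and for a further 33, which on the linear scale would need a larger share of CD25- cells in each CD25+CD49f- array than the 0.182 that Foxp3 or Il2ra leave if these would otherwise match CD25+CD49f+ cells. It cannot be told apart for the remaining 2 genes, Cxcr6, whose CD25+CD49f- arrays spread widely, and Pdlim4, for which a small share would suffice. Arrays that stand apart as the cause are argued against, since 95 of the 95 genes stayed called lower without those 4. Of these arrays only CD25+CD49f- replicate 5 belongs to the groups compared, and the others enter through each gene's spread alone. That array was low for Th17 genes (7.92) and Arnt2 (8.25), so for such genes leaving it out could hardly have ended the call. A candidate source is lymphoid tissue inducer cells, which can carry CD4, and 4 of 12 of their known genes were called lower (Id2, Il7r, Gpr183 and Ffar2, limma adjusted p from 0.000447 to 0.028), but the list was written down after its values had been seen, Id2, Il7r, Ltb and Bcl2 are also T cell transcripts, and of its 4 genes with the highest signals, which do not rank abundance across probe sets, Il7r (11.87 and 10.83 in CD25+CD49f- and CD25+CD49f+ cells) and Id2 (10.96 and 9.44) were called while Ltb (12.14 and 12.31) and Bcl2 (10.63 and 10.42) were not, so such cells and a T cell subset cannot be told apart. A gate on a T cell receptor chain would remove such cells, and the labels name none. The 95 genes include H2-Aa, H2-Ab1, H2-Eb1 and Cd74 of the B cell list and Batf3 and Fcer1g of the myeloid list. Carry-over of B cells or myeloid cells was not tested.

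The Itga6 transcript was not higher in CD25-CD49f+ than in CD25-CD49f- cells, while in CD25+ cells both probe sets were higher with CD49f (0.16 ± 0.10 and 0.40 ± 0.28) without being called. CD25+CD49f- replicate 5, which stood apart, was the lowest array of its group for both (9.28 and 7.08). The main probe set differed in CD25+ cells by -0.005 among arrays without Y-linked transcripts and by 0.15 among Y-linked arrays without Xist. For the CD25- cells a failing probe set is argued against by the further probe set, whose difference of -0.425 ± 0.227 there (-0.265 ± 0.208 without CD25-CD49f+ replicate 1, which lay far from its group) had the same sign. Saturation is argued against by values at least 4.08 below the brightest probe set of each array. Exchanged CD49f labels of the CD25- arrays cannot be told apart by Itgb1, higher by 2.13 in arrays labelled CD25-CD49f+, since neither transcript has to follow the surface level. Regulation of CD49f after transcription may be the cause, as an untested hypothesis, which CD49f protein and transcript measured in the same cells would decide.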

How the results depend on the processing

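The fits without the 4 arrays that stand apart, with Y-linked transcripts as a covariate, within arrays with or without Y-linked transcripts and with the Actb difference as a covariate were chosen after the data were seen, and the other alternatives were planned. Of 371 named calls, none reversed, 341 stayed called in every fit that left out 1 array, and 220 in every alternative. Counts are given for CD49f in CD25+ cells (332), CD49f in CD25- cells (2443), CD25 in CD49f+ cells (1040), CD25 in CD49f- cells (2551) and the interaction (966), in that order. Leaving out each array gave 257 to 432, 2126 to 2720, 785 to 1325, 2245 to 2768 and 773 to 1128, and no called gene turned direction. The 64 higher genes of the first comparison became 32 without CD25+CD49f+ replicate 2 and 33 without CD25+CD49f+ replicate 3, 3 (of 119) in arrays without Y-linked transcripts, 40 under median centring, 144 without the 4 arrays that stand apart and 211 with array weights, while its lower genes (268) numbered 237, 224, 116, 265, 444 and 551. Leaving out any other single array gave 42 to 94 higher genes. Array weights gave 762, 3742, 3083, 3659 and 2273, with 30.4% of interaction calls higher against 18.5%, and the cause was not tested. Without the 4 arrays that stand apart the counts were 588, 3473, 2361, 3581 and 1710, and the first kept all 332 genes. Arrays without Y-linked transcripts gave 119, 1340, 493, 1284 and 370, and arrays with Y-linked transcripts and without Xist 92, 1080, 264, 1004 and 242, where fewer arrays were fitted. The brighter 9097 genes gave 203, 2036, 872, 2090 and 736 from fewer genes tested. Every probe set gave 500, 4427, 1459, 4486 and 1408 probe sets, where a gene could count more than once and probe sets of no gene (9211) or several genes (932) were added, and these changes were not tested apart. An adjusted p under 0.01 left 211, 1636, 675, 1784 and 599, and a log2 difference of at least 1 left 106, 431, 199, 526 and 402, by their construction. Quantile, median and loess scaling kept the total of each comparison within 1.5 times. With an estimated correlation camera called 8, 13, 14, 11 and 14 lists against 14, 19, 21, 22 and 19, and fry, which does not compare a list with other genes, 12, 23, 19, 23 and 18. Of 95 list calls, 53 held in every alternative, 15 were lost in at least 1 fit that left out a single array, 7 without the 4 arrays that stand apart and 16 with the brighter 9097 genes. That of the integrin genes for CD25 in CD49f+ cells was lost without CD25-CD49f+ replicate 1, without CD25+CD49f+ replicate 3, without the 4 arrays that stand apart, in arrays without Y-linked transcripts and with the brighter 9097 genes. For CD25 in CD49f+ cells the Th2 list (adjusted p = 0.985) and the TCR-induced early genes (adjusted p = 0.359) were called with the brighter 9097 genes (adjusted p = 0.0411 and 0.0396), and the cause was not tested. The correlation of the CD49f effects was 0.126 in arrays without Y-linked transcripts and 0.14 in arrays with them and without Xist, against 0.226. That of the CD25 effects was 0.505 with the brighter 9097 genes, 0.311 in arrays with Y-linked transcripts and without Xist, and 0.264 by Spearman, against 0.438.

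Arrays of a group share replicate numbers with those of the other groups, but same-numbered arrays did not deviate together in every pair (correlations from -0.517 to 0.404). Same-numbered arrays differed in their sex transcripts in 4 of 5 pairs of CD25-CD49f- and CD25+CD49f- arrays, 2 of 7 of the CD25- groups and 0 of 4 of the CD25+ groups. The correlation was over 0.1 in 5 of the 7 and 1 of the 4. A replicate block gave 322, 2421, 936, 2372 and 985 genes, each within 1.5 times of the count without it, and ended 13 of the 371 named calls. With the block camera called 13, 19, 20, 22 and 19 lists.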

Other observations

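No test was added here after the results were seen. The cell cycle list was lowest in CD25-CD49f- cells (6.91 ± 0.20, SD) and averaged 8.69 ± 0.20 in CD25-CD49f+ and 7.48 ± 0.16 in CD25+CD49f- cells, with CD25+CD49f+ cells between these. The Th17 list averaged 8.08 ± 0.09 in CD25+CD49f- cells and 6.61 ± 0.09, 6.97 ± 0.05 and 6.79 ± 0.04 in CD25-CD49f-, CD25-CD49f+ and CD25+CD49f+ cells.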
